A study of Mus musculus with 15 samples.

How the data were processed

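MeDIP and RNA from J1 and TKO mouse ES cells were measured on Agilent arrays with 2 colours. Cells grew feeder-free for 2 passages, per the labels. Scanner files came from Agilent Feature Extraction (version 8.5, per the submitters' processing notes), and their intensity values are background-subtracted and dye-normalised, per the file headers: linearly on the MeDIP arrays and by LOWESS on the expression arrays. The authors' deposited value tables hold log10 ratios; those of the MeDIP arrays equal the scanner log ratio (red over green) within rounding, and the expression table is the mean log10 ratio of 3 arrays with replicate 2 turned, which correlated with the log2 ratios fitted here at r = 0.923 across genes. Deposited medians lay between -0.0102 and 0 on the MeDIP arrays and at -0.0158 for expression; their centring is not given in the sources used here. Other columns of the deposited files (flags and annotation) are not measurements and were used only as such.

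MeDIP ratios were log2(green/red) of the processed signals, that is J1 over TKO as the dyes are labelled, with each array centred on the median of its non-control probes and no loess. Control spots and spots marked as uneven were left out. A promoter was all probes of one transcript region, split at gaps over 2000 bp, with at least 3 probes, and its value the mean over probes. Part 1 had 40283 probes and part 2 had 40284. Ratios were tested against 0 with limma 3.58.1 (R 4.3.3), parts fitted apart and Benjamini-Hochberg over both. Expression used normexp (offset 50) and loess, with spots of a probe averaged and the brightest probe of a gene kept. Probes had to be well above background in J1 or TKO on all 3 arrays. The sign of replicate 2 was turned and no dye term was fitted.

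Recorded slide codes repeat between some arrays of a kind, which were taken as separate hybridisations. Because there is no dye swap on the MeDIP arrays, dye and line cannot be separated there. The labelled direction was fixed before the data were examined and was kept. The turned sign, the removal of chromosome 8 and promoters by file gene name without splitting were added after the data were seen. Accessions were named through a RefSeq table (GRCm38.p6), used for names only: 22072 of 41174 expression probes were named by accession and 17855 had no name. Of the promoters, 6751 on part 1 and 6748 on part 2 had 1 symbol, 430 and 485 had several, and 56 and 63 had none. The genome build of the probe positions is not given in the sources used here, so positions are not printed. A comparison with CpG content was planned and not run, since it needs sequence.

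Named promoters were the 12 highest on the labelled J1 side and the 8 lowest on the labelled TKO side with all 7 arrays on that side. Named genes were the 12 highest and 12 lowest expression calls with the same sign on all 3 arrays. Genes with a spot left out on an array, mostly replicate 3, were not eligible there, so Afp and Rhox6 enter through their lists. From both assays came the 10 highest and 5 lowest expression calls, and from each list up to 4 members with the largest change among calls. The Dnmt genes, Pou5f1 and Nanog were always included. Some items that these rules select are not reported here. Actb, Gapdh, Sycp3 and the promoter of Dazl were chosen after their values were seen. The fits were tested on simulated data with 200 changed features and independent errors, so no dye bias was simulated. At a log2 change of 0.7 the promoter fit recovered 99.5% on part 1 (7237 promoters) and 99.0% on part 2 (7296 promoters), with 0 false calls. With a median SD over arrays of 0.10, the size cut of 0.5 left little room for false calls. The simulated 0.7 lies above the highest ratio on the labelled J1 side (0.63), and recovery nearer the cut was not tested. The expression fit (13339 genes) recovered 0% at a log2 change of 0.5 and 41.0% at 1, with 0 false calls, so it can miss changes where few genes change.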

Results

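DNA methylation and gene expression were compared between J1, a wild-type mouse embryonic stem (ES) cell line, and TKO, an ES cell line that lacks the DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b. Methylated DNA was pulled down with an antibody (MeDIP) from 2 ug of genomic DNA, and the material from both lines was hybridised together on promoter arrays. The promoter design was split over a pair of arrays with different promoters, called part 1 and part 2, with 7 arrays of each, from different passages. RNA from both lines was compared on 3 expression arrays, which the study text calls replicates and which were deposited as 1 sample. Each array holds both lines, so its log ratio was taken as 1 replicate. Which cultures the expression arrays came from, and whether any share RNA, is not given in the sources used here, so their SD covers at least the spread between hybridisations. The number of arrays limits the precision. For single promoters and genes the p-values measure the spread between arrays. Fisher's exact tests, and tests of gene sets with a preset correlation between genes, are computed across promoters or genes instead. Only 1 J1 and 1 TKO line were compared, so no p-value covers the spread between lines of a genotype. On the MeDIP arrays between 88.2% and 99.7% of probes were well above background. On the expression arrays between 38.6% and 66.8% were, the lowest share being on replicate 3, where 8386 spots were marked as uneven.

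The direction of the MeDIP ratio rests on the dye labels. They put J1 in Cy3 and TKO in Cy5 on every array with no dye swap, and values at germ cell promoters raise doubt about them. Most promoters of the germ cell list, methylated in wild-type ES cells by textbook knowledge, lay on the side of the channel labelled TKO. Log2(J1/TKO) was -0.65 ± 0.19 (SD, n = 7) at Asz1, a germ cell gene, and -0.34 ± 0.11 at Sycp3, a meiotic gene. It was -0.72 ± 0.15 at Dppa3, which is in the pluripotency list and was well above background in J1 on all 3 expression arrays. At each, all 7 arrays were below 0. Asz1 and Dppa3 were named for their large change among calls and Sycp3 after its value was seen, so they are examples and not a test. The germ cell gene Dazl was closer to 0, at -0.15 ± 0.11 with 1 array above 0. Of 45 germ cell promoters 28 were below 0 and 3 above at an adjusted p under 0.05, whatever the size. At the housekeeping gene Gapdh it was 0.06 ± 0.09, and at Actb, whose probes lay -2437 bp from the annotated start at their nearest, 0.11 ± 0.12. All MeDIP ratios are therefore given by channel label, as "labelled J1" and "labelled TKO", and neither side is read as the methylated line.

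The first comparison asked which promoters were pulled down unequally from the lines. Among the lowest ratios on the labelled TKO side were Efcab5, with log2(J1/TKO) of -1.23 ± 0.32 (SD, n = 7), and Rhox2a, a reproductive homeobox gene of the X chromosome, with -1.16 ± 0.30. Hbs1l was at -1.13 ± 0.31, Abcg2, a membrane transporter, at -1.04 ± 0.33 and the olfactory receptor gene Olfr275 at -0.97 ± 0.28. The tiled probes of Rhox2a lay -2937 bp from the annotated start at their nearest. All of these were below 0 on each of the 7 arrays. Of these 5, only Rhox2a had enough probes well above background in both channels to give a value from them (-1.15), and Abcg2 had too few even for 1 channel or both, so the size of the other 4 ratios is uncertain. With normexp background correction in place of the Agilent processed signals, and median centring, Rhox2a was at -0.77 and still met both thresholds. Efcab5 (-0.39), Hbs1l (-0.35), Olfr275 (-0.17) and Abcg2 (-0.16) were all short of the size a call needs, Hbs1l (adjusted p = 0.0997) and Abcg2 (adjusted p = 0.0859) also of the adjusted p.

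Many more promoters passed the threshold towards the channel labelled TKO than towards the channel labelled J1. Of 7237 promoters on part 1, 177 lay on the labelled TKO side and 3 on the labelled J1 side. Of 7296 promoters on part 2, the counts were 203 and 9. The highest mean log2(J1/TKO) was 0.63, while the median SD over arrays was 0.10. A call needed a limma Benjamini-Hochberg adjusted p under 0.05 and a mean log2 ratio at least 0.5 from 0. With normexp background correction in place of the Agilent processed signals the labelled TKO side fell to 11 promoters on part 1 and 4 on part 2, and the labelled J1 side to 0 and 1. With probes above background in both channels the labelled TKO side had 74 and 113. The imbalance depended on the size cut: at any size past the adjusted p, 4506 promoters lay on the labelled TKO side and 3721 on the other.

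**Figure D1:**
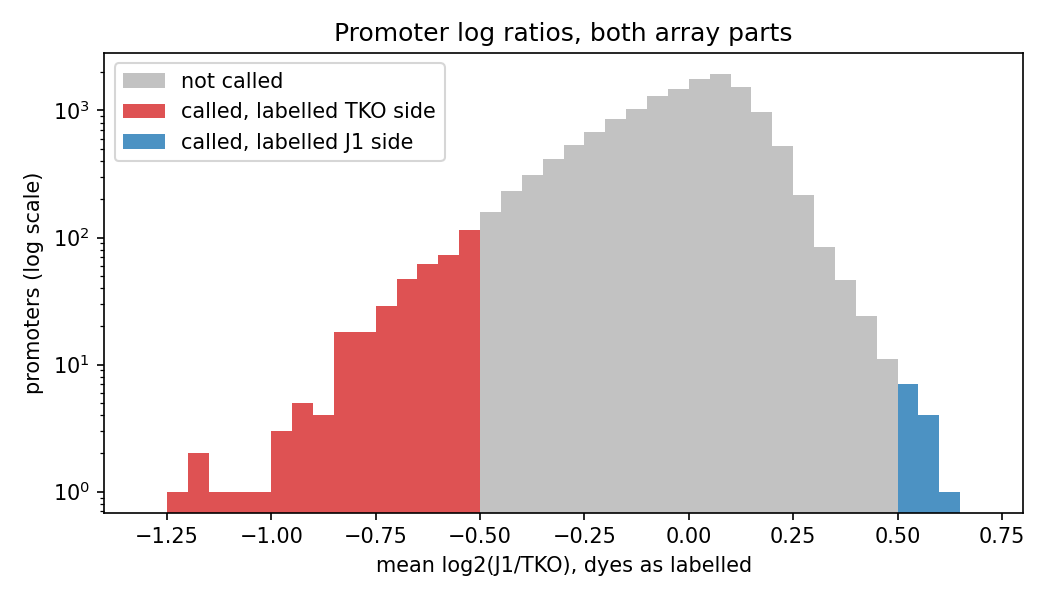
Number of promoters (log scale) by mean log2(J1/TKO) over 7 arrays, dyes as labelled, both array parts together, with called promoters in colour. The 380 promoters called on the labelled TKO side reach -1.23 and the 12 called on the labelled J1 side reach 0.63.

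Of the 12 promoters on the labelled J1 side, 9 lay on chromosome 8, which held 5.17% of the promoters tested (Fisher's exact test, two-sided, p = 4.8e-10). Among them were Pard3, a cell polarity gene, with log2(J1/TKO) of 0.63 ± 0.16 (SD, n = 7), Bst2 and Mvb12a, which share a region, with 0.57 ± 0.20, Tnks with 0.56 ± 0.09, Best2 with 0.52 ± 0.12, Dnase2a with 0.51 ± 0.14, Fgf20 with 0.51 ± 0.18, Anapc10 with 0.51 ± 0.18 and Tox3 with 0.50 ± 0.13. On other chromosomes were Slitrk1 on chromosome 14 with 0.60 ± 0.17, Nsfl1c on chromosome 2 with 0.59 ± 0.12, and Stap2 and Mpnd on chromosome 17 with 0.55 ± 0.13. With the median over probes Slitrk1 was at 0.077 (adjusted p = 0.267), and the region of Stap2 and Mpnd (0.19), Best2 (0.44) and Tox3 (0.497) were short of the size a call needs. Without chromosome 8, a choice made after these positions were seen, 1 promoter of part 1 and 2 of part 2 were called on this side. Probes of chromosome 8 as a whole also lay towards this side, with a median of 0.12 on part 1 and 0.09 on part 2. A shift of the whole chromosome and differences at single promoters were not separated in these calls. With normexp and median centring Slitrk1 (0.57) kept the size a call needs, and Pard3 (0.45), Tnks (0.37) and the others named here did not.

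**Figure D2:**
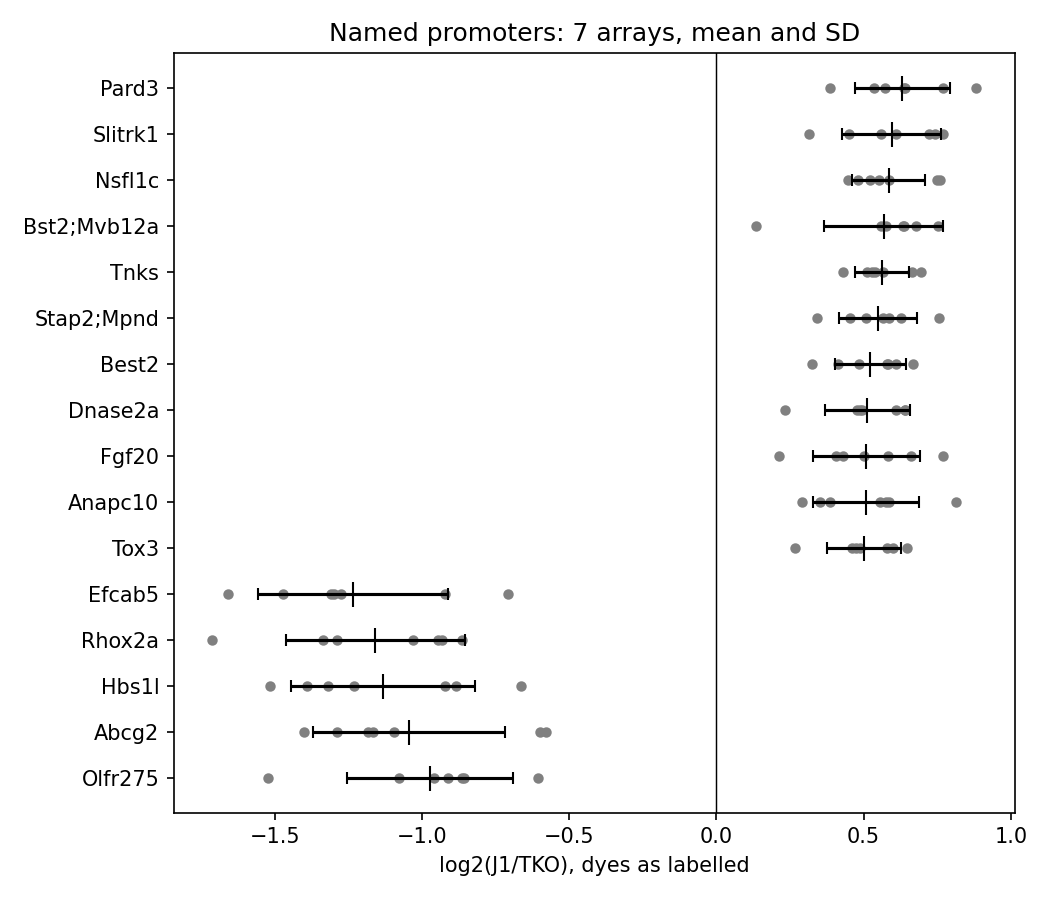
Log2(J1/TKO), dyes as labelled, of promoters named in the text. Points are the 7 arrays, ticks the mean and bars the SD. Means run from 0.63 at Pard3 down to -1.23 at Efcab5.

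Among the lists of genes fixed before the data were examined, 12 of 20 passed the test (cameraPR on limma statistics, preset correlation 0.01). The labelled TKO side held germ cell genes (45 promoters, median log2(J1/TKO) -0.16, adjusted p = 6.4e-05), the Rhox cluster (8 promoters, -0.23, adjusted p = 0.00112), tissue-specific genes (49 promoters, -0.16, adjusted p = 2.1e-05), olfactory receptors (631 promoters, -0.17, adjusted p = 1.1e-07), vomeronasal receptors (87 promoters, -0.14, adjusted p = 6.4e-05) and keratin-associated proteins (18 promoters, -0.26, adjusted p = 0.00112). None of these passed with an estimated correlation (adjusted p = 0.18 with an estimated correlation for germ cell genes and the Rhox cluster, and 0.145 for the rest). On the labelled J1 side were histone genes (38 promoters, 0.11, adjusted p = 0.00112), housekeeping genes (36 promoters, 0.07, adjusted p = 0.00396), germ layer markers (30 promoters, adjusted p = 0.0179), Polycomb developmental genes (49 promoters, adjusted p = 0.0169), defensins (25 promoters, adjusted p = 0.0293) and ribosomal proteins (73 promoters, adjusted p = 0.0465). None of these passed either (adjusted p = 0.547 with an estimated correlation for defensins and 0.145 for the rest). With normexp 5 lists passed in place of 12.

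Single members past the threshold were a minority of each list, as were the 380 of all 14533 promoters called on the labelled TKO side. Of the 8 Rhox promoters 2 were called, Rhox2a and Rhox4b (-0.62 ± 0.19). Of the germ cell promoters 2 were called, Asz1 and Fthl17e (-0.59 ± 0.12), and the count adjusted over the list alone was also 2. Of the olfactory receptors 27 were called, among them Olfr893 at -0.89 ± 0.33 and Olfr113 at -0.76 ± 0.27. The 4 tissue-specific genes were Fabp2 (-0.76 ± 0.23), Lyz1 (-0.70 ± 0.22), Gcg (-0.61 ± 0.19) and Fabp1 (-0.51 ± 0.04). Of the vomeronasal receptors 8 were called, with Vmn1r202 at -0.76 ± 0.24. Counts adjusted over the list alone were 27, 4 and 8 for these lists. The histone gene H1f5 (-0.64 ± 0.22) went against its list. The lists of pluripotency, trophoblast, primitive endoderm, fibroblast, imprinted, interferon response, p53 target and DNA methylation genes did not pass.

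The promoters of the methyltransferase genes themselves were not called. Log2(J1/TKO) was -0.12 ± 0.10 (SD, n = 7) at Dnmt1, though 0.066 with normexp and median centring and -0.012 with normexp and loess. It was -0.20 ± 0.08 at Dnmt3a, and 0.01 ± 0.17 at Dnmt3b, though -0.023 with mode centring. The Pou5f1 region, tiled no nearer than -4683 bp from the annotated start, had 0.22 ± 0.11. Nanog was not among the promoters or genes tested.

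The second comparison asked which RNAs differed between the lines. The dye labels of the expression arrays allow either order; with replicate 2 the swapped array, J1 in Cy5 on replicates 1 and 3 is the likely order. In that direction the deleted genes were lower in TKO. Log2(TKO/J1) was -2.51 ± 0.19 (SD, n = 3) for Dnmt3b, -2.36 ± 0.18 on 2 arrays for Dnmt3a and -1.07 ± 0.25 on 2 arrays for Dnmt1. Where the probes lie relative to the deleted parts was not examined. Dnmt3l, a cofactor of Dnmt3a and Dnmt3b, was higher at 0.77 ± 0.13, though at 0.44 with median centring in place of loess it did not pass (adjusted p = 0.253). With the Agilent processed signals Dnmt3b was at -3.77 and Dnmt3a at -3.61.

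Of 13339 genes tested, 2152 were higher and 2174 lower in TKO at a limma adjusted p under 0.05, and with a 2-fold change as well 200 were higher and 90 lower. Among genes with a symbol that were measured on all 3 arrays the strongest rises were in Rhox2a, with log2(TKO/J1) of 3.05 ± 0.59 (SD, n = 3), Krt8, an epithelial keratin, with 2.88 ± 0.33, Srgn with 2.58 ± 0.22, Dazl, a germ cell RNA-binding protein, with 2.41 ± 0.40, Dab2, an endocytic adaptor, with 2.38 ± 0.27, and Krt18, the keratin partner of Krt8, with 2.34 ± 0.18. Xlr reached 2.32 ± 0.44, Rhox9 2.29 ± 0.10, Stra8, a gene of meiotic entry, 2.25 ± 0.20 and Wfdc15a 2.08 ± 0.04. S100g was at least 4.57-fold and Prl4a1, a placental prolactin, at least 3.92-fold higher, since neither was well above background in J1 on any array; such bounds set the bright line's mean against the background limit, and the dyes are not balanced over 3 arrays. The order depended on the signals used: with the Agilent processed signals Xlr was at 3.96, above Rhox2a at 3.38 and Dab2 at 3.34, and S100g and Prl4a1 had the highest ratios of the genes named here.

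Among the same genes the strongest falls after Dnmt3b included Calml4 with -2.36 ± 0.27 (SD, n = 3), Ephx2, an epoxide hydrolase, with -2.32 ± 0.21, Bdh2 with -1.98 ± 0.18, Zscan4c, a marker of a rare ES cell state, with -1.72 ± 0.13, and Nr0b1, a pluripotency-associated nuclear receptor, with -1.56 ± 0.22. Pdcl2 was at -1.47 ± 0.26, Itgb7 at -1.45 ± 0.04, Polr3gl at -1.36 ± 0.18, Adam23 at -1.36 ± 0.07 and Ifitm1 at -1.36 ± 0.24. With the Agilent processed signals Bdh2 was at -3.03 and Zscan4c at -2.60. With a dye-effect term 1238 genes were higher and 1107 lower, and with median centring in place of loess 360 and 519. Without replicate 1 the counts were 1177 and 1090, and without replicate 2 they were 1097 and 1149.

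**Figure D3:**
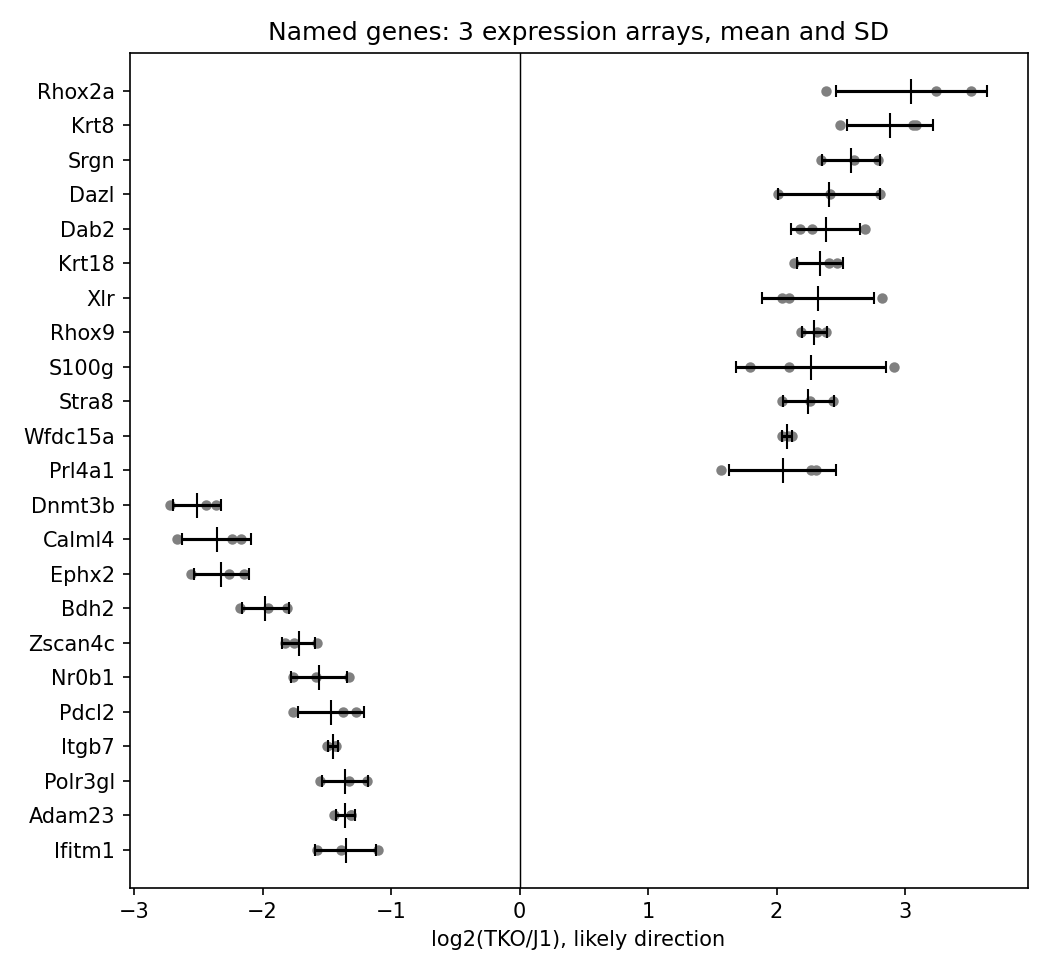
Log2(TKO/J1), in the likely direction, of genes named in the text. Points are the 3 arrays, ticks the mean and bars the SD. Rhox2a is highest at 3.05 and Dnmt3b lowest at -2.51.

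Of the fixed lists 17 had enough measured members, and 10 passed the test with the preset correlation. A gene not well above background in J1 on all 3 arrays was measured only if TKO was. That filter favours rises in lists of genes silent in J1, and the lists were not tested without it. Measured were 25 of 48 listed germ cell genes, 7 of 43 Rhox genes, 19 of 29 trophoblast and 17 of 24 primitive endoderm markers. Germ cell genes were higher, 19 of 25 measured and 0 lower, with a median log2(TKO/J1) of 0.60 (adjusted p = 4.5e-15; adjusted p = 0.23 with an estimated correlation). Besides Dazl and Xlr they included Asz1 at 2.07 ± 0.07 on 2 arrays and Tex101 at 1.77 ± 0.06. The Rhox cluster had 6 of 7 higher, with Rhox6 at 2.38 ± 0.13 on 2 arrays (adjusted p = 4.5e-25; adjusted p = 0.23 with an estimated correlation). Trophoblast markers had 16 of 19 higher (median 1.45, adjusted p = 1.6e-44) and primitive endoderm markers 16 of 17 (adjusted p = 4e-31), led by Afp at 3.86 ± 0.25 on 2 arrays and Dab2. Neither passed with an estimated correlation (adjusted p = 0.23 with an estimated correlation for each). The trophoblast list also holds Rhox6 and Rhox9. Fibroblast markers had 10 of 16 higher (adjusted p = 2.9e-07, and adjusted p = 0.23 with an estimated correlation), with Ccn1 at 1.57 ± 0.02, S100a4 at 1.42 ± 0.07 and Lox at 1.37 ± 0.17, each on 2 arrays. In the trophoblast, primitive endoderm and fibroblast lists 1 gene each was lower.

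Polycomb developmental genes had 12 of 18 higher (adjusted p = 5.9e-05, and adjusted p = 0.361 with an estimated correlation), with Hoxc9 at 1.19 ± 0.29, and tissue-specific genes 8 of 14 (adjusted p = 2.7e-05, and adjusted p = 0.506 with an estimated correlation), with Fgb, a fibrinogen chain, at 2.07 ± 0.08 on 2 arrays. Pluripotency genes had 10 of 23 lower and 2 higher (adjusted p = 0.00057, and adjusted p = 0.478 with an estimated correlation), with Tdh at -1.05 ± 0.05 on 2 arrays against Klf4 at 0.97 ± 0.17. Pou5f1 was at -0.72 ± 0.14 on 2 arrays, and at -0.75 with median centring, where it did not pass (adjusted p = 0.0657). The p53 targets had 9 of 19 lower (adjusted p = 0.00642, and adjusted p = 0.478 with an estimated correlation), with Psrc1 at -1.15 ± 0.39 and Mdm2 at -0.51 ± 0.20, each on 2 arrays. The DNA methylation list had 5 of 16 lower and 2 higher (adjusted p = 0.00496, downwards, and adjusted p = 0.624 with an estimated correlation) although its median was 0.03, and it holds the deleted genes. Adjusted over the list alone, 20 germ cell, 17 trophoblast and 16 primitive endoderm genes were higher. Imprinted, interferon response, germ layer, housekeeping, ribosomal, histone and olfactory receptor genes did not pass; the interferon and housekeeping lists had medians below 0 while their tests pointed up.

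The third comparison joined the assays. Of the genes with promoters on the labelled J1 side 12 were measured, and 8 were higher and 0 lower in TKO, with a median log2(TKO/J1) of 0.55 against 0.01 for the other genes (cameraPR p = 2.9e-05; p = 0.139 with an estimated correlation). The median lay at percentile 100 of 10000 random lists matched on brightness. The 8, all with promoters on chromosome 8, included Pard3 (1.28), Bst2 (1.26), Best2 (0.81), Tnks (0.69), Mvb12a (0.60) and Dnase2a (0.54), with Pard3 and Bst2 measured on 2 arrays. Without that chromosome only Nsfl1c (0.07), Mpnd (-0.028) and Stap2 (-0.14) were left, the last sharing a region with Mpnd, and the median was -0.028. The difference therefore rested on chromosome 8, whose genes as a whole were higher in TKO, and too few genes were left to judge the rest. The median was 0.41 without replicate 1 and 0.33 without replicate 2. For genes with promoters of any size past the adjusted p it was 0.0017 and the test did not pass. Detection in J1 was 71.4% of 14 such genes and 54.0% of the 13464 others (Fisher's exact test, two-sided, p = 0.284). For genes with promoters of any size past the adjusted p on the labelled J1 side it was 69.1% (Fisher's exact test, two-sided, p = 3.1e-108). The share of the other genes was not recorded at that setting, and the labelled TKO side was not tested at it.

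With the sign of the MeDIP ratio turned, a choice made after the data were seen, the set becomes the genes on the labelled TKO side. Of these, 113 of 374 (30.2%) were detected in J1, against 54.7% of the 13104 other genes (Fisher's exact test, two-sided, p = 6.4e-21). Of the 124 measured, 24 were higher and 14 lower in TKO, with a median log2(TKO/J1) of 0.03 (cameraPR p = 0.044; p = 0.817 with an estimated correlation). The test with an estimated correlation covered only the 73 measured on all 3 arrays. For the 124, a difference from the other genes was not detected in the share higher (Fisher's exact test, two-sided, p = 0.815) or lower (p = 0.213). The strongest rises were in Afp (3.86), Rhox2a (3.05), Sct (2.12), Asz1 (2.07), 1700018B24Rik (1.74), Ifi27 (1.67), Prl7d1 (at least 2.93-fold, not well above background in J1), Ccl2 (1.29), Fabp1 (at least 1.94-fold, likewise) and Drd4 (1.05). The strongest falls were in Dner (-1.31), Sinhcaf (-0.87), Pcmtd1 (-0.77), Acad11 (-0.64) and Nt5dc1 (-0.63). Afp, Sct, Asz1, 1700018B24Rik, Ifi27, Fabp1, Pcmtd1 and Acad11 were measured on 2 arrays.

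By chromosome, chromosome 8 had the MeDIP median furthest from 0 on each part, which holds in either direction of the ratio, and the expression median furthest above that of other genes. Its probes had a median log2(J1/TKO) of 0.12 ± 0.04 (SD, n = 7) on part 1 and 0.09 ± 0.01 on part 2, dyes as labelled, and its genes had a median log2(TKO/J1) 0.17 ± 0.04 (SD, n = 3) above that of other genes. Chromosome Y probes, on part 1, were at 0.10 ± 0.11 (SD, n = 7) with 6 of 7 arrays above 0 (exact two-sided sign-flip p = 0.0469, adjusted 0.0793).

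**Figure D4:**
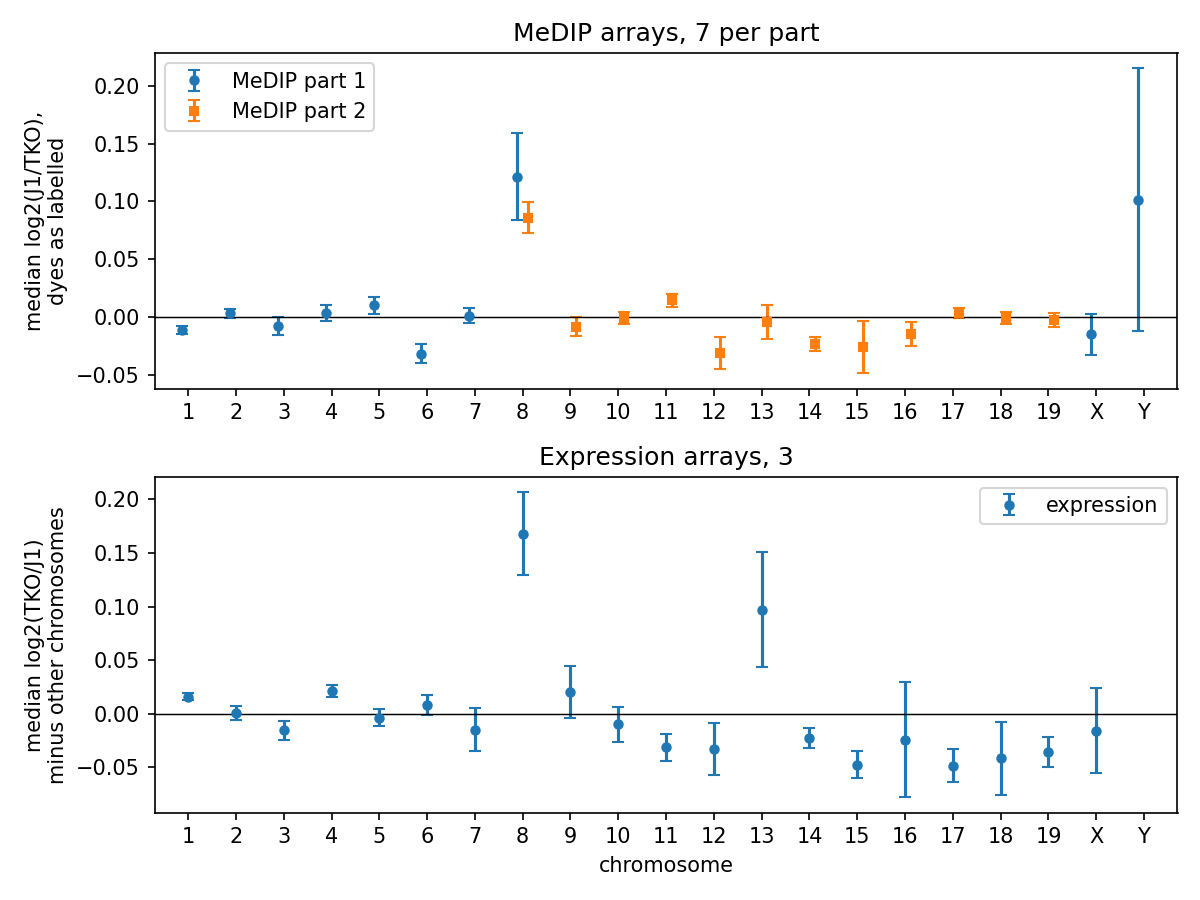
Median log2 ratio by chromosome, upper panel MeDIP (dyes as labelled, 7 arrays per part), lower panel expression (3 arrays, relative to the other chromosomes). Points are means over arrays and bars the SD. Chromosome 8 is at 0.12 and 0.09 in the upper panel and 0.17 in the lower one.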

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

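The test on the germ cell list was chosen after its result was seen. The tests of sign patterns, of loess and of chromosome 8 expression were fixed before theirs were, but after the counts and the MeDIP chromosome medians had been seen. Of 34 groups of 7 arrays examined, 6 had 1 array far from the others, where chance gives about 1 in 20. On part 1, replicate 6 had 91.2% of red spots well above background and 465 uneven spots, each far from the other arrays. On part 2, replicate 5 had 2681 uneven spots. Single arrays stood apart at the Bst2 and Mvb12a promoter (0.14 on replicate 1), at Dnase2a (0.23 on replicate 7) and at Pou5f1 (0.45 on replicate 6).

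A candidate explanation for the direction of the MeDIP ratios is that the dyes were recorded the wrong way round: the germ cell list, methylated in wild-type ES cells by textbook knowledge, had a median log2(J1/TKO) of -0.16 with all 7 arrays below 0. The shift was not particular to that list. Olfactory receptors (-0.17), vomeronasal receptors (-0.14), tissue-specific (-0.16) and keratin-associated genes (-0.26) also had all 7 arrays below 0, while histone (0.11) and housekeeping genes (0.07) lay above. A comparison with CpG content was not run. Chromosome 8 probes lay towards the channel labelled J1 (0.12 ± 0.04 on part 1 and 0.09 ± 0.01 on part 2, SD, n = 7, exact two-sided sign-flip p = 0.0156, the smallest 7 arrays can give, adjusted 0.0344), whereas chromosome 8 genes were higher in TKO by 0.17 ± 0.04 on all 3 arrays. If DNA and RNA of a chromosome shift together, the channel labelled J1 held TKO DNA. On chromosome 13 they did not: 95 genes were higher and 37 lower in TKO, with MeDIP probes at -0.0045 ± 0.015 (SD, n = 7). The labels allow either order of the expression dyes, but the reverse of the one used is argued against, since it would put the deleted genes Dnmt3b (-2.51 ± 0.19, n = 3), Dnmt3a (-2.36 ± 0.18, n = 2) and Dnmt1 (-1.07 ± 0.25, n = 2) higher in TKO. Where their probes lie relative to the deleted parts was not examined. Brightness-dependent dye bias was tested by loess: after normexp and loess 14 promoters lay on the labelled TKO side and 1 on the other. This argues against it for the promoters still called, though these counts are small. The 380 called before fell about as far with normexp and median centring (11 on part 1 and 4 on part 2). The test therefore cannot tell what made the calls that were lost. The swap stays a hypothesis, since it was found on the same data, a dye bias cannot be excluded without a dye swap, and no biological explanation was tested.

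Chance was also examined by turning the signs of arrays. On part 1, 1 of 64 splits gave as many promoters as the 180 observed, the real one itself, and the highest other gave 2. On part 2 it was again 1 of 64, with 212 observed and 56 at most otherwise. A share of 1 in 64 is the smallest that these splits can give. It argues against random signs of the arrays on both parts. A dye bias shared by all arrays would give the same result, so the test cannot tell that apart from a difference between the lines. With 3 expression arrays there are only 4 splits, too few for a share under 0.05; the real one gave 4326 genes, the highest other 0, and 1 split reached the real count.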

How the results depend on the processing

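Values are in the order labelled J1 part 1, part 2, labelled TKO part 1, part 2; causes were not tested. Counts were 0, 1, 11 and 4 with normexp and median centring, 0, 1, 10 and 4 with normexp and loess, 11, 27, 297 and 307 from 1 probe up, 324, 343, 2771 and 2821 for single probes, 1845, 1876, 2235 and 2271 at a log2 threshold of 0, and 0, 0, 4 and 2 at a threshold of 1. On the labelled J1 side part 1 gave 6 without centring, 7 with the median over probes and 5 with array weights, and part 2 gave 5 with mode centring. With probes above background in both channels the labelled TKO side had 74 and 113. With the sign of the ratio turned, added later, counts were 177, 203, 3 and 9, and without chromosome 8, also added later, the labelled J1 side had 1 and 2. Leaving out 1 array gave 4 to 13 on part 2 of that side, the 4 without replicate 6. A slide block could be estimated on part 2 only and gave 10 and 207 there.

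Genes higher and lower in TKO numbered 360 and 519 with median centring, 1238 and 1107 with a dye term, and 200 and 90 with a 2-fold threshold; leaving out 1 array gave 1097 to 1954 and 1090 to 1809. Of the lists, 0 promoter and 0 expression lists passed with an estimated correlation, and 5 promoter lists with normexp. Dnmt3l (0.44, adjusted p = 0.253) and Pou5f1 (-0.75, adjusted p = 0.0657) did not pass with median centring. For genes on the labelled J1 side the median was 0.55 with an estimated correlation (p = 0.139), 0.0017 at a log2 threshold of 0 (p = 0.593), -0.028 without chromosome 8 and 0.33 to 0.51 leaving out 1 array. Detection was 69.1% at a threshold of 0 (Fisher's exact test, two-sided, p = 3.1e-108) and, at the threshold of 0.5, 30.2% with the sign turned. Uncalled promoters near 0 changed sign: Dnmt1 was 0.066 with normexp and median centring; Dnmt3b was -0.023 with mode centring, -0.0035 with probes above background in 1 channel or both, and -0.027 to 0.046 leaving out 1 array; a Dnmt3l region was -0.015 with mode centring and -0.0023 to 0.051 leaving out 1 array. No paired analysis was possible because the 2 array parts carry no promoter in common; this holds for single promoters, and list medians join the parts by replicate number. Not run were the GC correction, which needs sequence, fits within a scan date, since no date holds more than 1 array of a part, and slide blocks on part 1 and the expression arrays, which could not be estimated.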

Other observations

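Imprinted genes, a list fixed before the data were examined, went both ways in TKO. Of 25 measured, 6 were higher and 4 lower, and the list did not pass the test (adjusted p = 0.0751). The largest changes in log2(TKO/J1) were in Cdkn1c, a growth inhibitor, at 1.81 ± 0.12, Dlk1 at 1.32 ± 0.08, Meg3 at 0.95 ± 0.24 and Peg10 at 0.92 ± 0.02, with Dlk1 on 3 arrays and the others on 2.

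The test of every chromosome was planned before the data were examined. Its reason was that a copy number difference between the lines would shift a whole chromosome in both assays. Copy number itself was not measured, and on the MeDIP arrays it cannot be told apart from methylation. The question about chromosome 8 expression was written after the MeDIP medians had been seen. Of 490 measured chromosome 8 genes 192 were higher and 38 lower in TKO (camera on limma statistics, adjusted p = 6.8e-06). Promoters on chromosome 8 exceeded the others by 0.15 on part 1 and 0.10 on part 2, by 0.10 and 0.06 after normexp and loess, and by 0.10 and 0.04 after normexp and median centring. Chromosome 13 genes were higher in TKO too (95 higher and 37 lower of 328, adjusted p = 0.0247), and its MeDIP probes were at -0.0045 ± 0.015 (SD, n = 7). Other chromosomes with the same exact sign-flip p as chromosome 8 had MeDIP medians between -0.03 and 0.01.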
